A study of Rattus norvegicus with 4 samples.

How the data were processed

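Nuclei from the area postrema and the nucleus tractus solitarius, adjoining regions of the dorsal hindbrain that receive signals from the gut and the blood, were profiled by droplet single-nucleus RNA sequencing in 4 male Sprague Dawley rats. Per the labels, each rat weighed about 400 g, received saline intraperitoneally when the lights went off and was killed under anaesthesia 6 h later. Tissue from 3 punches per rat was pooled, and libraries were made with the 10x Genomics 3′ chemistry and sequenced on an Illumina NovaSeq. The 4 rats form 1 group, saline control, and are called replicates 1 to 4. The design holds no comparison between groups of rats, so the comparisons below are between classes of nuclei within the same animals.

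The deposited values were raw UMI counts per gene and droplet barcode, made with Cell Ranger 3.1 on the Rnor_6.0 build, per the submitters' processing notes. The annotation release, the setting for intronic reads and the strand setting are not given in the sources used here. Each deposited matrix held counts for 32883 genes and 6794880 barcodes, so empty droplets were included and nuclei had to be called here. Genes were taken by the symbols and Ensembl identifiers of the deposited files, and 195 symbols carried by more than 1 identifier were kept apart. Coordinates are not printed, because the gene table at hand belongs to another build.

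A barcode was called a nucleus with at least 1000 UMIs, at least 500 genes and under 5% of its UMIs from the 13 mitochondrial genes. The UMI and gene minimums passed 25814, 19431, 21701 and 27709 barcodes in replicates 1 to 4, and the mitochondrial limit left 7349, 5818, 8858 and 6028. Doublet scores came from Scrublet in scanpy 1.11.5. Its automatic threshold marked 2, 2, 811 and 0 barcodes and so did not work in replicates 1, 2 and 4. Therefore the 6% of barcodes with the highest scores were removed in every rat, a rule set after that result was seen. Barcodes with 100 to 700 UMIs served as empty droplets for the level of free RNA. Their median was 541, 592, 596 and 607 UMIs in replicates 1 to 4, so the alternative minimum of 500 UMIs lies within their range. From the level of Ttr, a choroid plexus transcript, free RNA was estimated to make up 20.3% ± 4.31 (SD, n = 4) of the UMIs of neurons, 31.6% ± 4.21 of those of astrocyte-like nuclei and 38.6% ± 6.00 of those of oligodendrocyte-like nuclei.

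Genes were divided at random into a clustering set of 16329 genes, which held all cell type markers, and a testing set of 16541 genes, which held all genes of the lists below. No gene used for clustering and no marker was therefore tested, although genes of both sets took part in the ranking of leading genes. The Gfral cluster was chosen by Gfral, which was left out of the calls of that contrast. Counts of the clustering set were scaled to 10000 per nucleus and log-transformed, and 2000 variable genes were scaled within each rat. Clusters came from 30 principal components, 15 neighbours and the Leiden method at resolution 1 (scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2). All nuclei gave 39 clusters, and the neurons clustered by themselves gave 26. Clusters were named X-like from 21 marker sets. A class scored the mean over its markers of the level relative to the highest cluster, with a minimum of 0.3 and, except for neurons, a mean log2 fold of at least 1. Clusters stayed unnamed where markers of another class led, or where another class that passed scored at least 0.6 of the best and, unless neurons were involved, had at least 0.4 of its log2 fold. Neuronal clusters were typed by another rule: cholinergic-like or monoaminergic-like at a score of at least 0.5, otherwise by the best of the excitatory, inhibitory and cholinergic scores if it was at least 0.1 and the next was under 0.4 of it. A minimum number of the markers of that type also had to be detected. By this last condition cluster 24 stayed untyped, with an excitatory score of 0.165 and an inhibitory score of 0.0566. The excitatory-like clusters 6, 11 and 25 scored only 0.157, 0.253 and 0.2099, and the monoaminergic-like clusters 13 and 16 scored 0.474 and 0.558 for excitatory neurons beside 0.554 and 0.57 for monoaminergic ones. The markers were fixed beforehand, and the scoring limits were set after the clusters had been seen.

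UMI counts were summed per rat and class. The sums were compared with edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr, rat as a block; R 4.3.3), and p-values were adjusted by Benjamini-Hochberg over all genes tested. A gene was called at an adjusted p under 0.05, and all adjusted p-values of single genes in the report come from this test. Classes with under 10 nuclei in a rat were left out of the sums. The contrasts were neurons against astrocyte-like nuclei, inhibitory-like against excitatory-like neurons, oligodendrocyte-like nuclei against their precursors, the neuronal cluster with the highest Gfral level against all other neurons, and, over 69 receptors, neurons against the mean of the other classes with at least 10 nuclei in each rat. In the Gfral contrast the prior degrees of freedom were estimated as infinite, which makes very small p-values unreliable as sizes, so none is printed for it. Folds are TMM-scaled values from the fit, and CPM values are means over rats of each sum divided by its own total. In each contrast the tissue of each rat gives both sums, so the sums pair by animal. Deviations of the 2 sums of a rat correlated between 0.0921 and 0.546 over the 4 contrasts of 2 sums, and the highest correlation with another rat was 0.0751.

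Named genes were the 10 with the largest fold change each way among those called, changed the same way in all 4 rats, with a mean CPM of at least 20 in the higher class and a gene symbol that is not a locus identifier. Up to 2 members each way of every gene list were added, those with the lowest p. Not every gene named by this rule is reported here. In addition 19 receptors and peptides were reported whatever their values. The 14 gene lists covered energy balance receptors, nausea-related transmitter receptors, neuropeptides, GABA and glycine receptors, glutamate receptors, voltage-gated potassium channels, hindbrain transcription factors, immediate early genes, circadian clock genes, cholesterol biosynthesis, the cell cycle, glucose and lactate handling, the extracellular matrix and adhesion genes of perineuronal nets, and cytokine receptors. Of their 351 genes, 343 were found by symbol, and Vipr1, Kcnb2, Kcnd2, Hoxa2, Hoxa4, Hoxa5, Ccnb2 and Pcx were not analysed here. Lists with at least 5 tested members were tested with camera (limma 3.58.1), once with a preset correlation of 0.01 and once with an estimated correlation, and adjusted over the lists of a contrast. With 0 counts in a class, a fold was bounded by 3 counts over the class's summed UMIs. With 1 to 3 counts, the ratio is given with its 95% Poisson interval, except where free RNA had been subtracted.

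Joint detection of 2 receptor genes in neuronal nuclei was measured as a Mantel-Haenszel odds ratio over 10 depth strata per rat, for 12 pairs. The rat was the unit, in an exact two-sided sign-flip test whose smallest p with 4 rats is 0.125. Shares of nuclei with a UMI were also computed after thinning each nucleus to 1000 UMIs, a depth every called nucleus reached. Intervals of shares are exact binomial (Clopper-Pearson) at 95%, and the floor of a share is 3 nuclei over the rat's total. Both cover counting error only.

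The markers, lists, contrasts, tests, named-gene rule and a first set of alternatives were fixed before the data were examined. These alternatives were UMI minimums of 500 and 2000, doublets kept, genes scaled over all rats together, another random division of the genes, resolution 2, median-of-ratios factors, DESeq2 1.42.0, no filter on low counts, no block, leaving out each rat in turn, 10% of each sum subtracted as free RNA, and thinning before co-detection. Added after seeing the data were a mitochondrial limit of 10%, removal of clusters with under 10 nuclei in 2 or more rats, subtraction of free RNA by each sum's Ttr level, and library sizes alone without scaling factors.

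The tests were tested on simulated data with 200 changed genes and a fixed spread added between rats. The changed genes were drawn only from those above a minimum mean count per sum, so the shares called do not cover genes of low counts. At a true fold of 2, the share of changed genes called was 90% for neurons against astrocytes (6749 genes), 99% for inhibitory against excitatory neurons (6256 genes), 85% for oligodendrocytes against precursors (4212 genes), 54% for the Gfral cluster (6460 genes) and 94% for the panel (4413 genes). At a true fold of 4 the shares were 97%, 100%, 92%, 81% and 99%. Between 6 and 8 unchanged genes were called per contrast. The added spread was the same in all sums of a rat, so the block takes it up. The rest of the spread followed the fitted trend, so genes that vary more than the trend are not covered. For co-detection, simulated neuronal nuclei with a true log2 odds ratio of 2 gave 2.04 ± 0.16 (SD), and with a true value of 0 gave −0.19 ± 0.48. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.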

Results

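Droplet libraries of single nuclei were made from the area postrema and the nucleus tractus solitarius of 4 male rats that had received saline. The rats formed 1 group, so each comparison was made between classes of nuclei of the same animals, with the rat as the unit of replication (n = 4). The libraries of replicates 1 to 4 held 104751227, 80516678, 97013802 and 91349090 UMIs. Of these 19.8%, 19.6%, 29.95% and 14.9% lay in the nuclei kept. These were 6908, 5469, 8327 and 5666 nuclei, 26370 in all, with a median of 2521.5, 2535, 2928 and 2150 UMIs and 1610, 1631, 1757 and 1430.5 genes per nucleus. Levels are CPM values of the summed UMIs of a class, as the mean ± SD over 4 rats. Differences are log2 fold changes with their standard errors.

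Neurons were the most abundant class, at 55.3% ± 8.90 of nuclei (SD, n = 4), followed by oligodendrocyte-like nuclei at 15.03% ± 4.04 and astrocyte-like nuclei at 5.91% ± 1.94. Oligodendrocyte precursor-like nuclei made up 2.78% ± 0.193, choroid plexus epithelium-like nuclei 1.62% ± 0.1251, microglia-like nuclei 1.05% ± 0.753 and fibroblast-like nuclei 1.03% ± 0.671 (0.568% with another random division of the genes and 0.585% at a clustering resolution of 2). Committed precursor-like (0.858% ± 0.150), endothelial-like (0.648% ± 0.213), perivascular macrophage-like (0.379% ± 0.198), ependymal-like (0.166% ± 0.138; 0.102% without replicate 3) and mural-like nuclei (0.106% ± 0.0789) were rarer. The share of neurons was 55.2% (95% exact binomial interval 54.0 to 56.4) in replicate 1 and 62.0% (60.7 to 63.3) in replicate 2. It was 42.8% (41.7 to 43.9) in replicate 3 and 61.3% (60.0 to 62.5) in replicate 4, so the rats differed by more than counting error. This share leaves out cerebellar granule-like nuclei, which were counted as a class of their own. Part of the low share in replicate 3 comes from that split. Nuclei with the genes of cerebellar granule neurons were found in replicate 1 (211 nuclei, 3.05%, interval 2.66 to 3.49) and replicate 3 (1054 nuclei, 12.7%, interval 11.95 to 13.4). Replicate 4 held 1 such nucleus, and replicate 2 held 0 of 5469, which allows a share of up to 0.0549% by the limit of 3 nuclei and 0.0674% by the exact binomial interval. Unnamed clusters held 11.5%, 8.81%, 6.74% and 17.7% of the nuclei of replicates 1 to 4. Shares of glial classes moved with the depth and mitochondrial limits. At a minimum of 2000 UMIs oligodendrocyte-like nuclei made up 5.53%, astrocyte-like nuclei 3.87%, unnamed nuclei 18.5% and microglia-like nuclei 0.130%. Microglia-like nuclei made up 3.59% at a minimum of 500 UMIs, and 2.22% with a mitochondrial limit of 10%, which also gave 0.426% ependymal-like nuclei. The minimum of 500 UMIs lies within the range taken for empty droplets. With doublets kept, unnamed nuclei made up 17.2%.

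**Figure D1:**
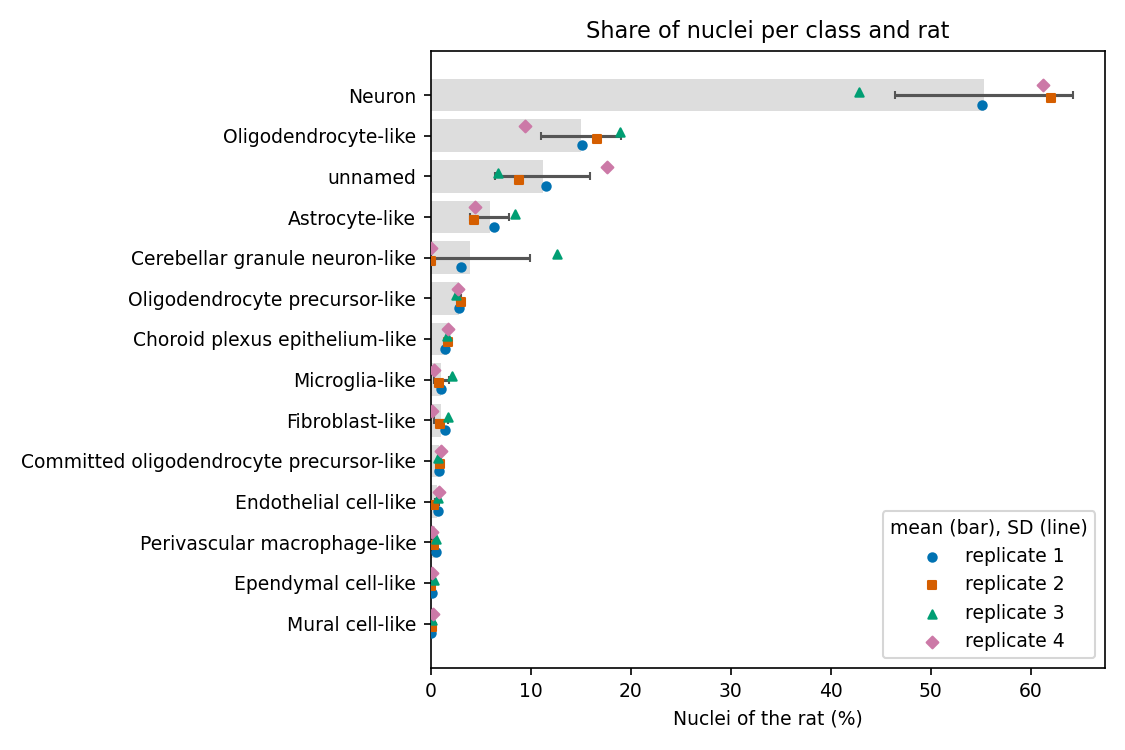
Percent of nuclei in each named class, with bars for the mean over 4 rats, lines for the SD and a point for each rat. Neurons, with cerebellar granule-like nuclei counted apart, lie between 42.8% and 62.0% in every rat. Granule-like nuclei reach 12.7% in replicate 3 and 0% in replicate 2.

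Clustered by themselves, 34.9% ± 6.65 of neurons were inhibitory-like (4996 nuclei), with genes for making and loading GABA or glycine, and 26.7% ± 2.26 were excitatory-like (3801 nuclei), with vesicular glutamate transporters. Monoaminergic-like neurons, with genes for catecholamine or serotonin synthesis and transport, made up 4.98% ± 0.585 (707 nuclei). Cholinergic-like neurons made up 3.25% ± 1.46 (462 nuclei) and had the highest median depth, 5027 UMIs against 2974 in excitatory-like and 2695 in inhibitory-like neurons. No type was assigned to 29.6% ± 7.27 of neurons, and in a further 0.543% ± 0.264 glial genes led the cluster. The inhibitory-like neurons included 1 cluster of 439 nuclei with 163, 6, 269 and 1 nuclei in replicates 1 to 4.

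Neurons were first compared with astrocyte-like nuclei. Glra3, a glycine receptor subunit, stood at 201 ± 22.7 CPM in neurons and 6.59 ± 0.740 CPM in astrocyte-like nuclei (log2 fold change 4.65, SE 0.17, adjusted p = 4.1e-16, n = 4). The adhesion molecules Dscam (4.65, SE 0.17) and Lrfn5 (4.21, SE 0.13; 1497 ± 77.1 against 66.2 ± 13.02 CPM) and the netrin receptor Unc5d (4.13, SE 0.22) were higher in neurons as well. Gli2, a transcription factor of Hedgehog signalling, stood at 169 ± 10.1 CPM in astrocyte-like nuclei and 2.11 ± 0.567 CPM in neurons (log2 fold change −6.54, SE 0.16, adjusted p = 1.0e-18). Fgfr3, a fibroblast growth factor receptor (−6.28, SE 0.29), the peptide transporter Slc15a2 (−5.54, SE 0.13) and the water and glycerol channel Aqp9 (−5.48, SE 0.16) were lower in neurons in 4 of 4 rats. Of 6877 genes tested, 2018 were higher and 1975 lower in neurons, and 3676 of the calls had the same direction in 4 of 4 rats. With library sizes alone in place of TMM factors, the median log2 fold change of all genes moved from 0.03 to 0.27, and the split became 2737 higher and 1464 lower (65.2% higher against 50.5%). Of 71 named genes, 33 moved more than 1.5-fold when free RNA was subtracted by Ttr (Gli2 to −7.62, Aqp9 to −7.73), 23 at a clustering resolution of 2 (Lrfn5 to 2.66) and 15 under a mitochondrial limit of 10%. With another random division of the genes 19 of 63 did (Glra3 to 2.52, Dscam to 2.65).

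Among the fixed lists, voltage-gated potassium channels and glutamate receptors were higher in neurons as groups. Of 19 potassium channel genes tested, 14 were higher and 1 lower (15 and 1 adjusted over the list alone; camera adjusted p = 4.3e-05, adjusted p = 0.479 with an estimated correlation). Examples were the M-current subunits Kcnq3 (3.23, SE 0.14) and Kcnq5 (3.44, SE 0.18). Of 22 glutamate receptor genes, 15 were higher and 4 lower (15 and 5 adjusted over the list alone; adjusted p = 0.00068, adjusted p = 0.479 with an estimated correlation). The metabotropic receptors Grm8 (4.02, SE 0.13) and Grm7 (3.78, SE 0.14) were higher, and Grm3 (−0.70, SE 0.10) was lower. Nausea-related transmitter receptors had 10 of 16 higher and 2 lower (11 and 2 adjusted over the list alone; adjusted p = 0.0102, adjusted p = 0.547 with an estimated correlation). The serotonin receptors Htr4 (3.70, SE 0.20) and Htr2c (2.93, SE 0.12) were among them. Hindbrain transcription factors had 14 of 30 higher and 2 lower (the same adjusted over the list alone; adjusted p = 0.0197, adjusted p = 0.547 with an estimated correlation), such as Zfhx4 (2.65, SE 0.16). This call was lost with free RNA subtracted by Ttr (adjusted p = 0.0902). Neuropeptides had 14 of 29 higher and 3 lower (the same adjusted over the list alone; adjusted p = 0.0428, adjusted p = 0.547 with an estimated correlation), such as Scg2 (1.13, SE 0.12) and Penk (0.98, SE 0.12). In neurons Scg2 (475 ± 27.8 CPM) and Penk (360 ± 18.3 CPM) lay below empty droplets (547 ± 63.9 and 440.5 ± 99.4 CPM), and with free RNA subtracted by Ttr their values were 4.22 and 3.31. The neuropeptide call was lost in 6 settings, among them the fits without replicate 1 (adjusted p = 0.0685), without replicate 3 (0.0959) and without the rat as a block (0.0816). Gcg, which encodes proglucagon, was lower in neurons (−1.60, SE 0.35; −0.90 and not called without the block). Its 11.9 ± 12.9 CPM in neurons and 23.4 ± 18.3 CPM in astrocyte-like nuclei lay below the 27.7 ± 23.0 CPM of empty droplets.

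Circadian clock genes were lower in neurons as a group, with 1 of 18 higher and 16 lower (the same adjusted over the list alone; adjusted p = 2.9e-05, adjusted p = 0.479 with an estimated correlation). The nuclear receptor Rorb stood at 64.4 ± 4.68 CPM in neurons and 960.4 ± 176 CPM in astrocyte-like nuclei (−4.10, SE 0.11). Npas2, a partner of the clock protein Arntl, was also lower (−4.35, SE 0.12), whereas Clock itself was higher (0.54, SE 0.12). Glucose and lactate handling had 2 of 21 higher and 14 lower (the same adjusted over the list alone; adjusted p = 0.00221, adjusted p = 0.479 with an estimated correlation). Examples were the glycogen phosphorylase Pygm (−3.39, SE 0.16) and the glycolytic regulator Pfkfb3 (−2.53, SE 0.13). Cytokine receptors had 0 of 16 higher and 6 lower (the same adjusted over the list alone; adjusted p = 0.0294, adjusted p = 0.547 with an estimated correlation), such as Lifr (−2.08, SE 0.15). A mitochondrial limit of 10% ended this call (adjusted p = 0.0833). Cholesterol biosynthesis had 2 of 23 higher and 8 lower (the same adjusted over the list alone; adjusted p = 0.0442, adjusted p = 0.578 with an estimated correlation), including Msmo1 (−1.16, SE 0.10) and Cyp51 (−1.14, SE 0.10). This call was lost in 10 settings, most of all with free RNA subtracted by Ttr (adjusted p = 0.628). Others were the fits without replicate 1, 3 or 4 (adjusted p = 0.0741, 0.115 and 0.0522) and without the block (0.131). No call was made for energy balance receptors (13 of 28 higher, 7 lower; 14 and 7 adjusted over the list alone) or for GABA and glycine receptors (10 of 18 higher, 6 lower; 10 and 7 adjusted over the list alone). Immediate early genes (3 of 13 higher, 5 lower), the cell cycle (3 of 16 higher, 4 lower; 3 and 3 adjusted over the list alone) and perineuronal net genes (6 of 11 higher, 5 lower) had none either. Immediate early genes had a median of −0.23 and a mean of 0.14. With a mitochondrial limit of 10%, GABA and glycine receptors were called (adjusted p = 0.0210).

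Inhibitory-like neurons were then compared with excitatory-like neurons. Rbm44, an RNA-binding protein gene, stood at 48.0 ± 23.7 CPM in inhibitory-like and 2.70 ± 0.585 CPM in excitatory-like neurons (log2 fold change 4.19, SE 0.18, adjusted p = 3.1e-15, n = 4). The transcriptional corepressor Skor2 (3.30, SE 0.21) and the dopamine receptor Drd2 (2.57, SE 0.13; 48.4 ± 4.57 against 8.10 ± 0.891 CPM) were also higher in inhibitory-like neurons. So were the opioid-like peptide precursor Pnoc (2.37, SE 0.13) and the natriuretic peptide Nppc (2.24, SE 0.09; 124 ± 39.4 against 26.9 ± 2.27 CPM). The secretin receptor Sctr stood at 32.9 ± 7.03 CPM in excitatory-like and 1.72 ± 0.308 CPM in inhibitory-like neurons (−4.39, SE 0.20, adjusted p = 1.4e-14). Cacna2d1, a calcium channel subunit, was also lower in inhibitory-like neurons (−3.84, SE 0.07; 61.9 ± 9.87 against 853 ± 45.8 CPM). The LIM-homeobox gene Lhx2 (−3.83, SE 0.23), the nicotinic receptor subunit Chrna5 (−2.93, SE 0.17) and the peptide precursor genes Nts (−2.70, SE 0.11) and Grp (−2.45, SE 0.24) were lower in inhibitory-like neurons in 4 of 4 rats. Of 6314 genes tested, 787 were higher and 765 lower, and 1408 of the calls had the same direction in 4 of 4 rats. Without the rat as a block 644 genes were called, by DESeq2 650, and without replicate 1 1008. Of 59 named genes, 9 moved more than 1.5-fold at a clustering resolution of 2 (Rbm44 to 2.95, Cacna2d1 to −2.81) and 11 when free RNA was subtracted by Ttr (Nts to −5.34, Grp to −5.09).

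Glutamate receptors were called higher in inhibitory-like neurons as a group, with 9 of 22 higher and 1 lower (10 and 1 adjusted over the list alone; camera adjusted p = 2.6e-05, adjusted p = 0.357 with an estimated correlation). The other 12 were neither, and the list's median log2 fold change was 0.05 and its mean 0.35. The kainate receptor genes Grik3 (2.30, SE 0.10) and Grik2 (0.47, SE 0.04) were higher, and the AMPA receptor gene Gria2 (−0.23, SE 0.04) was lower, a call that was lost without the block (−0.24). Circadian clock genes were lower, with 1 of 17 higher and 7 lower (2 and 9 adjusted over the list alone; adjusted p = 0.00156, adjusted p = 0.248 with an estimated correlation), such as Rorb (−1.54, SE 0.12) and Per3 (−0.68, SE 0.06). Hindbrain transcription factors were called lower (adjusted p = 8.3e-06, adjusted p = 0.248 with an estimated correlation) although 7 of 26 were higher and 9 lower (9 and 9 adjusted over the list alone). Their median was 0.05 and their mean −0.45. Zfhx3 (−2.48, SE 0.08) and Meis1 (−1.69, SE 0.05) were lower, and Gbx1 (3.42, SE 0.35) and Tfap2a (1.22, SE 0.25; 1.16 and not called by DESeq2) higher. Among lists with no call, energy balance receptors had 5 of 22 higher and 6 lower, with Ret (1.74, SE 0.14) and the incretin receptor Gipr (1.56, SE 0.17) higher. Gfral, the receptor of GDF15, was lower (−1.65, SE 0.15; 9.27 ± 0.689 against 30.6 ± 6.01 CPM). Nausea-related transmitter receptors had 5 of 16 higher and 2 lower (8 and 3 adjusted over the list alone), and the substance P receptor Tacr1 was lower (−1.49, SE 0.14; −0.58 at a resolution of 2). Neuropeptides had 8 of 28 higher and 10 lower (8 and 11 adjusted over the list alone), with Penk (1.22, SE 0.05) higher and Cck (−1.68, SE 0.09) lower. At a resolution of 2 the nausea-related receptors (adjusted p = 0.000225), neuropeptides (0.00473), GABA and glycine receptors (0.0074) and energy balance receptors (0.0126) were called as lists. A minimum of 2000 UMIs did so for the nausea-related receptors (0.0221) and potassium channels (0.0386).

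GABA and glycine receptors had 9 of 17 higher and 4 lower in inhibitory-like neurons (10 and 5 adjusted over the list alone), with Gabrb1 higher (0.46, SE 0.05) and Gabra5 lower (−0.88, SE 0.08). Potassium channels had 8 of 19 higher and 8 lower (10 and 8 adjusted over the list alone), with Kcnc2 higher (0.87, SE 0.06) and Kcnip1 lower (−2.16, SE 0.07). Without replicate 3 this list was called (adjusted p = 0.0452). The cell cycle list had 3 of 10 higher and 0 lower (5 and 0 adjusted over the list alone), glucose and lactate handling 1 of 18 higher and 4 lower (3 and 4), and perineuronal net genes 1 of 11 higher and 3 lower (1 and 5). Immediate early genes had 1 of 11 higher, cholesterol biosynthesis 1 of 23 higher and 1 lower, and cytokine receptors 2 of 11 higher and 2 lower. The median and mean had opposite signs for potassium channels (0.17 and −0.07), perineuronal net genes (−0.04 and 0.02) and cytokine receptors (−0.05 and 0.01).

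Oligodendrocyte-like nuclei were compared with their precursors. Hapln2, a link protein of the nodal matrix, stood at 1741 ± 359.6 CPM in oligodendrocyte-like nuclei and 48.3 ± 15.1 CPM in precursors (log2 fold change 5.46, SE 0.18, adjusted p = 6.5e-23, n = 4). Dock5, a Rac exchange factor (5.51, SE 0.24), was also higher. Synj2, an inositol phosphatase, had 0 counts in precursors, which makes it at least 45.4-fold higher by the limit of 3 counts over the summed precursors (28.1-fold without replicate 3). Slc16a10, an amino acid transporter, was at least 14.7-fold higher by the same limit (9.51-fold without replicate 3). Chst11, a chondroitin sulfotransferase, stood at 626 ± 123 CPM in precursors and 6.70 ± 2.01 CPM in oligodendrocyte-like nuclei (−6.49, SE 0.17, adjusted p = 1.6e-25). The collagen gene Col5a3 (−6.30, SE 0.18), the adhesion gene Dscam (−5.91, SE 0.17), the ryanodine receptor Ryr3 (−5.80, SE 0.15) and the proliferation gene Top2a (−5.56, SE 0.38; −4.27 without replicate 3) were lower in oligodendrocyte-like nuclei in 4 of 4 rats. Of 4340 genes tested, 945 were higher and 1049 lower, with the same direction in 4 of 4 rats for 1895 of the calls. Library sizes alone moved the median log2 fold change of all genes from 0.03 to −0.20 and the split to 569 higher and 1427 lower (28.5% higher against 47.4%). A minimum of 2000 UMIs left 3112 genes to test and 1294 calls. A mitochondrial limit of 10% moved 21 of 61 named genes more than 1.5-fold (Hapln2 to 4.23, Dock5 to 4.09), and free RNA subtracted by Ttr moved 32 of 59.

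Cholesterol biosynthesis was higher in oligodendrocyte-like nuclei, where 19 of 19 genes tested were higher (the same adjusted over the list alone; camera adjusted p = 4.3e-08, adjusted p = 0.322 with an estimated correlation), with a median log2 fold change of 1.13. Cyp51 (1.66, SE 0.14; 262 ± 33.0 against 98.2 ± 33.5 CPM) and Msmo1 (1.48, SE 0.13), enzymes of the late sterol pathway, were examples. Of 18 glutamate receptor genes, 2 were higher and 15 lower (the same adjusted over the list alone; adjusted p = 2.6e-08, adjusted p = 0.169 with an estimated correlation). Grm5 (−3.71, SE 0.14) and Grm7 (−3.29, SE 0.12) were lower and Grm3 was higher (4.84, SE 0.18; 2854 ± 297 against 122 ± 48.8 CPM). Of 15 GABA and glycine receptor genes, 0 were higher and 14 lower (the same adjusted over the list alone; adjusted p = 2.1e-06, adjusted p = 0.164 with an estimated correlation), such as Gabrg3 (−3.54, SE 0.14). Potassium channels had 3 of 16 higher and 10 lower (the same adjusted over the list alone; adjusted p = 0.0313, adjusted p = 0.2997 with an estimated correlation), with Kcnq5 (−3.92, SE 0.20) lower and Kcnq3 (1.62, SE 0.12) higher. This call was lost in 7 settings, among them free RNA subtracted by Ttr (adjusted p = 0.502) and doublets kept (0.361). A resolution of 2 (0.330) and the fit without replicate 2 (0.101) were others.

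No call was made for energy balance receptors (4 of 10 higher, 4 lower), nausea-related transmitter receptors (0 of 5 higher, 4 lower), neuropeptides (2 of 16 higher, 1 lower) or hindbrain transcription factors (2 of 11 higher, 6 lower). The same held for circadian clock genes (0 of 11 higher, 5 lower; 1 and 5 adjusted over the list alone), the cell cycle (1 of 5 higher, 2 lower), glucose and lactate handling (5 of 15 higher, 5 lower), perineuronal net genes (2 of 7 higher, 4 lower) and cytokine receptors (3 of 8 higher, 1 lower). Calcrl, the receptor of the CGRP family, stood at 514 ± 150.2 CPM in precursors and 12.8 ± 2.53 CPM in oligodendrocyte-like nuclei (−5.18, SE 0.16). The proteoglycan Cspg5 was also lower (−5.12, SE 0.25), whereas the adiponectin receptor Adipor2 was higher (3.28, SE 0.32). In the cell cycle list, Anln, which encodes an actin-binding protein of the division furrow, was higher (4.95, SE 0.25). The median and mean had opposite signs for energy balance receptors (0.43 and −0.28), the cell cycle (0.16 and −0.72), glucose and lactate handling (0.03 and −0.06) and cytokine receptors (−0.03 and 0.56). Only 3 immediate early genes were tested in this contrast, too few for a list test; 1 was higher and 1 lower (2 and 1 adjusted over the list alone).

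The neuronal cluster with the highest Gfral level held 314 excitatory-like nuclei (84, 73, 97 and 60 in replicates 1 to 4) and was compared with all other neurons. Nts, which encodes neurotensin, stood at 888 ± 171 CPM in the cluster and 27.4 ± 9.53 CPM in other neurons (log2 fold change 5.02, SE 0.12, n = 4). Npff, which encodes neuropeptide FF, was at 498 ± 187 against 25.3 ± 4.31 CPM (4.29, SE 0.12), and its receptor gene Npffr2 was higher too (4.75, SE 0.27). The secretin receptor Sctr (5.57, SE 0.17; 348 ± 44.8 against 7.28 ± 0.964 CPM), the urocortin receptor Crhr2 (5.03, SE 0.37) and the nicotinic subunits Chrna3 (5.13, SE 0.17) and Chrna5 (4.67, SE 0.18) were higher in 4 of 4 rats. The kainate receptor gene Grik1 (−4.72, SE 0.29; 9.08 ± 7.13 against 213 ± 24.4 CPM) was lower. Plscr5 had 0 counts in the cluster, which makes it at least 8.16-fold lower by the limit of 3 counts (5.38-fold without replicate 2 and 4.64-fold without replicate 3). Of 6613 genes tested, 433 were higher and 606 lower, and 960 of the calls had the same direction in 4 of 4 rats. With DESeq2 688 genes were called. The sums of the cluster held 120585 to 408126 UMIs per rat. With another random division of the genes 17 of 50 named genes moved more than 1.5-fold (Sctr to 4.86, Chrna3 to 4.42, Crhr2 to 4.31, Grik1 to −3.73), and with free RNA subtracted by Ttr 13 of 57 did.

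Receptors for glutamate, GABA and the nausea-related transmitters were lower in this cluster as groups. Of 22 glutamate receptor genes, 3 were higher and 14 lower (4 and 16 adjusted over the list alone; camera adjusted p = 1.4e-10, adjusted p = 0.0688 with an estimated correlation), such as Grm8 (−2.79, SE 0.14), with Grik5 higher (0.67, SE 0.13). Nausea-related transmitter receptors had 1 of 16 higher and 8 lower (1 and 10 adjusted over the list alone; adjusted p = 1.7e-05, adjusted p = 0.232 with an estimated correlation). The serotonin receptors Htr2c (−3.08, SE 0.17; 59.0 ± 26.8 against 472 ± 75.5 CPM) and Htr4 (−2.59, SE 0.27) were lower, and the cannabinoid receptor Cnr1 higher (0.72, SE 0.19; 0.46 and not called without replicate 3). GABA and glycine receptors had 1 of 16 higher and 9 lower (1 and 11 adjusted over the list alone; adjusted p = 0.000146, adjusted p = 0.146 with an estimated correlation), with Gabrb2 (−2.54, SE 0.20) lower and Gabrg3 (1.02, SE 0.10) higher. Perineuronal net genes had 0 of 11 higher and 5 lower (0 and 6 adjusted over the list alone; adjusted p = 0.000995, adjusted p = 0.232 with an estimated correlation), with a median of −1.66, or −1.24 with the gene of 0 counts at its bound. Hindbrain transcription factors had 9 of 28 higher and 4 lower (11 and 7 adjusted over the list alone; adjusted p = 0.0450, adjusted p = 0.232 with an estimated correlation), with Meis2 (1.68, SE 0.10) and Pbx3 (1.64, SE 0.11) higher. Their median was 0.13 and their mean −1.20, or −0.16 with 4 genes of 0 counts at their bounds. This last call was lost in 6 settings, among them the fits without replicate 3 or 4 (adjusted p = 0.0741 and 0.0735). With another random division of the genes, Htr2c, Grm8 and Gabrb2 stood at −0.85, −1.57 and −0.93, and the call of GABA and glycine receptors was lost (adjusted p = 0.251).

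Among lists with no call in the Gfral-rich cluster, energy balance receptors had 5 of 27 higher and 6 lower (6 and 8 adjusted over the list alone), with the orexin receptor Hcrtr2 (−2.71, SE 0.44) and Igf1r (−1.04, SE 0.17) lower. Without replicate 2 the value of Hcrtr2 was −3.33, and without the block the list was called (adjusted p = 0.0218). Neuropeptides had 5 of 28 higher and 7 lower, with Sst (−1.41, SE 0.15) and Penk (−1.25, SE 0.14) lower. With free RNA subtracted by Ttr, Penk stood at −2.17, and Sst, left with 2 counts in the cluster, was higher in other neurons by a ratio of 91.5. The 2 counts are a remainder of the subtraction and no observed count. The ratio therefore depends on the estimated share of free RNA and has no counting interval. Sst stood at 562 ± 55.5 CPM in empty droplets. Potassium channels had 3 of 19 higher and 4 lower (3 and 8 adjusted over the list alone), immediate early genes 0 of 11 higher and 3 lower, and circadian clock genes 2 of 17 higher and 3 lower. Cholesterol biosynthesis had 2 of 23 higher and 0 lower, glucose and lactate handling 1 of 18 higher and 2 lower (1 and 3 adjusted over the list alone), and cytokine receptors 0 of 13 higher and 1 lower. The cell cycle list had 0 of 12 higher and 1 lower, with a median of −0.33, or −0.25 with the gene of 0 counts at its bound. Signs differed for neuropeptides (median −0.31, mean 0.01) and clock genes (median 0.01, mean −0.21), and the camera direction of energy balance receptors was up although their median was −0.30 and their mean −0.16.

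Of the 69 receptors of energy balance and nausea signalling, 20 passed the count filter in a joint fit of 8 classes, and neurons were compared with the mean of the other 7. In neurons 11 receptors were higher and 5 lower, with the same counts adjusted over the list alone. The 7 nausea-related receptors tested were all higher. They were Htr4 (4.24, SE 0.18), Tacr1 (3.61, SE 0.34; 4.33 without replicate 2), Drd2 (2.36, SE 0.23), Adra1a (1.93, SE 0.15), Htr2c (1.57, SE 0.16), Oprm1 (1.25, SE 0.11) and Cnr1 (0.98, SE 0.13). Of 13 energy balance receptors, 4 were higher, 5 lower and 4 neither. Hcrtr2, an orexin receptor, was higher (3.89, SE 0.30; 4.51 without replicate 3; 41.5 ± 5.14 CPM in neurons), as was Ntrk2, the receptor of BDNF (0.95, SE 0.10). Calcrl (−2.13, SE 0.19) and Ramp1 (−1.55, SE 0.16), which form the CGRP receptor together, were lower in neurons, with 514 ± 150.2 and 236 ± 79.5 CPM in precursor-like nuclei. The contrast averages classes on a log scale. Htr2c, Casr, Adra1a, Oprm1, Ntrk2 and Ret were called higher although another class exceeded neurons. Choroid plexus-like nuclei (5676 ± 578 CPM of Htr2c) and committed precursor-like nuclei (113 ± 19.6 CPM of Casr) stood above neurons (464 ± 75.7 and 3.52 ± 2.23 CPM), as did astrocyte-like nuclei for Adra1a (118 ± 24.9 against 84.7 ± 6.57 CPM), Ntrk2 (729 ± 28.4 against 475 ± 18.3) and Ret (50.6 ± 9.62 against 36.1 ± 2.59). Oprm1 was at 110.0 ± 25.4 CPM in microglia-like nuclei and 66.2 ± 8.38 CPM in neurons. Casr (2.30, SE 0.95, adjusted p = 0.0317) was not called by DESeq2 (0.90) or without replicate 3 (1.21), and stood at 3.20 and 3.11 without replicate 1 and 2. Without replicate 3 Ret (0.51 with all rats) and Adipor2 (−0.73) stood at 0.27 and −0.50 and were not called. Igf1r (−0.41, SE 0.09) was lower, and Adipor1 (−0.32, SE 0.12) lost its call without replicate 1 or 3 (−0.29 and −0.28). Free RNA subtracted by Ttr moved 8 of 18 receptors more than 1.5-fold. The receptors tested numbered 67 with 47 called when no count filter was used, and 27 were called with a mitochondrial limit of 10%. Library sizes alone moved the median log2 fold change of all genes in this fit from 0.04 to 0.19, and the share of calls higher in neurons from 54.1% to 65.2%.

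**Figure D2:**
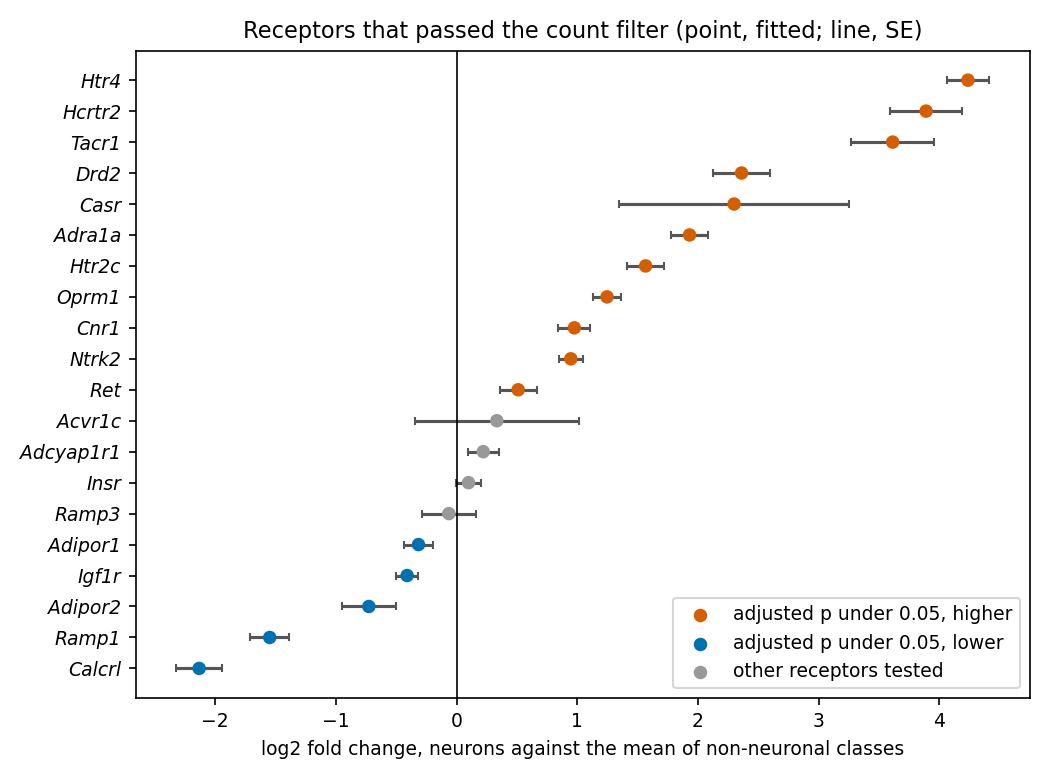
Log2 fold change of 20 receptor genes in neurons against the mean of 7 other classes, with lines for the standard error and colour for the adjusted p (n = 4 rats). Htr4 lies farthest to the higher side at 4.24 and Calcrl farthest to the lower side at −2.13.

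Of the 19 receptors and peptides reported whatever their values, Casr, Calcr and Gipr had 56.8%, 54.96% and 42.4% of their neuronal UMIs in 1 cluster. Lepr (100%) and Ghsr (46.15%) had UMIs in only 1 and 6 nuclei of their highest clusters. The lowest shares were those of Pomc (5.16%), Insr (5.80%), Htr3a (7.18%) and Tacr1 (8.68%). Shares of nuclei with a UMI are means over the 4 rats. Gfral (ENSRNOG00000032063) stood at 19.4 ± 2.27 CPM in neurons and at 347 ± 138 CPM in the excitatory-like cluster 15, followed by 130.2 ± 63.2 and 107 ± 23.9 CPM in the monoaminergic-like clusters 13 and 16. Cluster 15 exceeded cluster 13 in 4 of 4 rats (exact sign-flip p = 0.13, the smallest that 4 rats allow). The highest clusters of each gene were picked by their means over these same rats. Such counts of rats and p-values, here and for Glp1r, therefore give no independent support for the order of the clusters. In cluster 15, 30.3% of nuclei had a Gfral UMI at a median depth of 2814 UMIs, against 0.206% of oligodendrocyte-like nuclei at 1688 UMIs. Thinned to 1000 UMIs the shares were 19.5% and 0.119%. Glp1r (ENSRNOG00000001152), the GLP-1 receptor, stood at 3.65 ± 1.01 CPM in neurons, 43.4 ± 22.4 CPM in cluster 13 and 24.4 ± 7.24 CPM in cluster 15, and cluster 13 was higher in 3 of 4 rats (exact sign-flip p = 0.375). A Glp1r UMI was seen in 10.2% of cluster 13 (42 of 409 nuclei in all, median 2436 UMIs) and 0.0874% of oligodendrocyte-like nuclei (5 of 4065 in all, median 1688 UMIs). Calcr (ENSRNOG00000010053), the calcitonin receptor, reached 365 ± 148 CPM in cluster 16 and 189 ± 66.6 CPM in cluster 13, against 15.2 ± 7.09 CPM in all neurons and 0.857 ± 0.604 CPM in oligodendrocyte-like nuclei. Its UMIs were in 27.3% of cluster 16 (median 3176 UMIs) and 0.149% of oligodendrocyte-like nuclei. Among neuronal clusters Casr (ENSRNOG00000002265), the calcium-sensing receptor, was highest in cluster 13 (81.7 ± 56.6 CPM, 159 in replicate 3 and 23.4 in replicate 4). Committed precursor-like nuclei had more, at 113 ± 19.6 CPM.

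Gipr (ENSRNOG00000015860) stood at 169 ± 19.1 CPM in the inhibitory-like cluster 9 and 80.7 ± 11.3 CPM in cluster 15 (4 of 4 rats, exact sign-flip p = 0.13), against 10.9 ± 2.84 CPM in all neurons. Here too the clusters were picked by the same values, so the p-value gives no independent support for their order. A Gipr UMI was in 27.1% of cluster 9 (median 2650 UMIs) and 0.623% of oligodendrocyte-like nuclei (median 1688 UMIs). Ret (ENSRNOG00000014751), the signalling partner of Gfral, was highest in cluster 9 (177 ± 18.6 CPM), but its 36.1 ± 2.59 CPM in all neurons lay below the 43.9 ± 9.76 CPM of empty droplets. Cartpt (ENSRNOG00000017712) stood at 690.3 ± 144 CPM in cluster 9 and 202 ± 19.8 CPM in cluster 3, and Cck (ENSRNOG00000019321) at 285 ± 39.98 CPM in cluster 15 and 154 ± 54.1 CPM in cluster 17. Across all neurons both lay below empty droplets (107 ± 13 against 214 ± 33.0 CPM for Cartpt and 38.6 ± 2.64 against 89.1 ± 4.70 CPM for Cck). Tacr1 (ENSRNOG00000005853) was at 83.3 ± 25.0 CPM in cholinergic-like neurons and 28.5 ± 3.97 CPM in all neurons. Ramp3 (ENSRNOG00000053766), a partner of Calcr, was at 47.1 ± 9.21 CPM in cluster 13 and 36.1 ± 12.8 CPM in cluster 18, with 11.03 ± 1.13 CPM in all neurons, 23.6 ± 4.23 CPM in oligodendrocyte-like nuclei and 19.7 ± 3.17 CPM in empty droplets. Insr (ENSRNOG00000029986) was at 70.6 ± 5.61 CPM in neurons and 109 ± 49.6 CPM in endothelial-like nuclei. Levels of Htr3a (ENSRNOG00000006595; 3.90 ± 0.894 CPM in neurons, 4.44 ± 1.197 in empty droplets), Mc4r (ENSRNOG00000018692; 2.41 ± 0.396 and 2.88 ± 1.39) and Pomc (ENSRNOG00000012686; 7.37 ± 2.94 and 19.5 ± 4.98) lay below those of empty droplets over all neurons. Free RNA was estimated at 20.3% of neuronal UMIs, so this does not mean that it gave all of these levels. Gcg (ENSRNOG00000005498) reached 146 ± 187 CPM in the untyped cluster 19, from 8 of 246 nuclei. UMIs of Cckar (ENSRNOG00000043124), Ghsr (ENSRNOG00000024119), Npy (ENSRNOG00000046449) and Lepr (ENSRNOG00000023664) were seen in 22, 13, 3 and 1 of 14161 neuronal nuclei. These are too few to describe the distribution of the genes, and why they were so few was not tested.

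**Figure D3:**
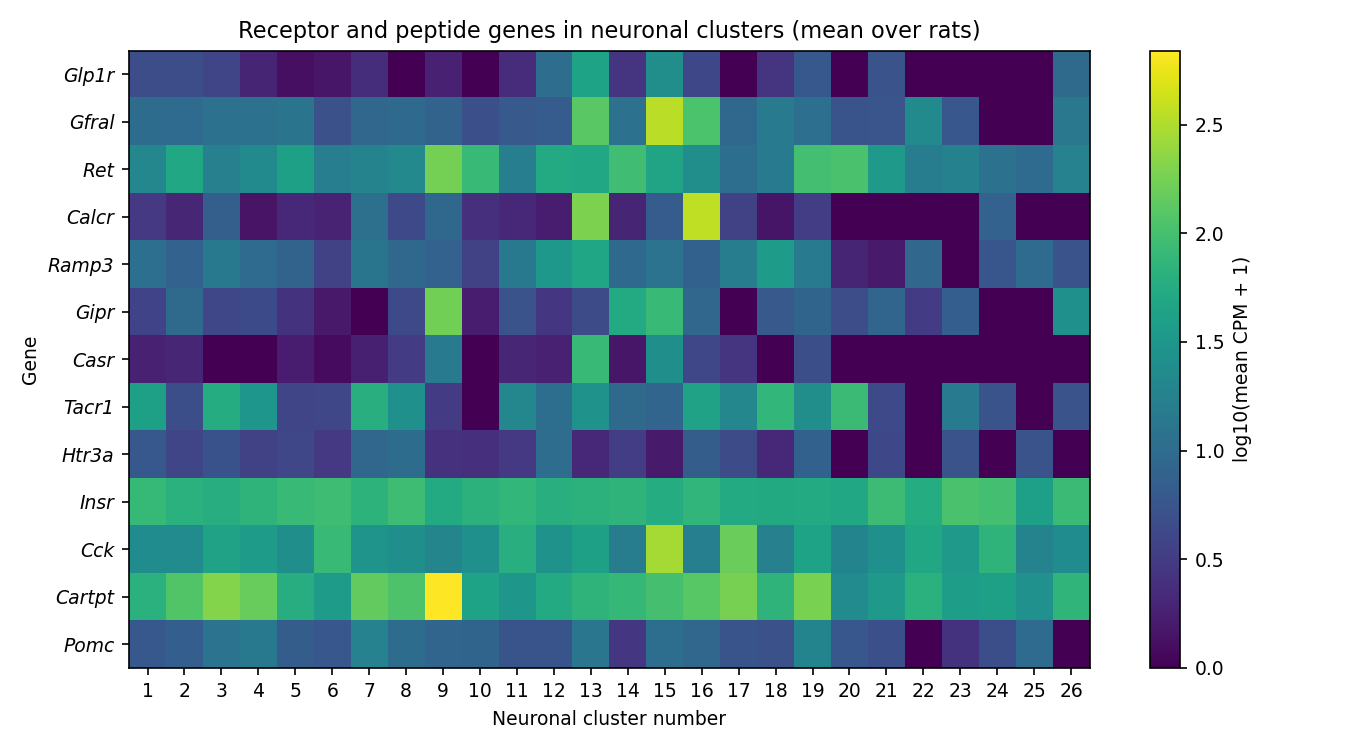
Mean CPM of 13 genes in the 26 neuronal clusters, on a colour scale of log10(CPM + 1). Gfral is brightest in cluster 15 (347 CPM), Calcr in cluster 16 (365 CPM), Glp1r in cluster 13 (43.4 CPM) and Gipr in cluster 9 (169 CPM).

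Several receptor genes were detected together in neuronal nuclei more often than their separate frequencies gave at the same depth. Glp1r and Casr shared 21 nuclei against 1.47 expected (odds ratio 30.5; log2 odds ratio 4.93 ± 1.41), and Gfral and Casr 34 against 5.05 (odds ratio 10.6; 3.41 ± 0.76). For Glp1r and Casr the odds ratio ran from 13.5 in replicate 3 to 114 in replicate 4. Gfral and Calcr shared 43 nuclei against 11.5 (odds ratio 4.84; 2.28 ± 0.59), Glp1r and Gfral 24 against 7.03 (4.11; 2.04 ± 0.56), and Calcr and its partner Ramp3 28 against 9.52 (3.36; 1.75 ± 0.24). Each of these 5 odds ratios exceeded 1 in 4 of 4 rats (exact sign-flip p = 0.13, the smallest possible; adjusted over 7 pairs 0.175), so none could pass a threshold of 0.05. Gfral and Ret shared 67 nuclei against 61.8 (odds ratio 1.15; 0.20 ± 0.30; exact p = 0.375, adjusted 0.4375), and Cck and Calcr 24 against 27.1 (0.642; −0.64 ± 1.13; exact p = 0.5, adjusted 0.5). Glp1r with Calcr (7 nuclei against 3.31) and Glp1r with Gipr (10 against 5.25) had no value in every rat. Glp1r with Cckar was seen in 0 nuclei against 0.252 expected, and Lepr, with 1 positive nucleus, in 0 with Glp1r or Calcr. Within clusters the log2 odds ratios were lower, at 2.95 ± 2.42 for Glp1r and Casr, 1.79 ± 1.01 for Gfral and Casr, 1.23 ± 0.43 for Calcr and Ramp3, 0.84 ± 0.53 for Glp1r and Gfral and 0.47 ± 0.77 for Gfral and Calcr.

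**Figure D4:**
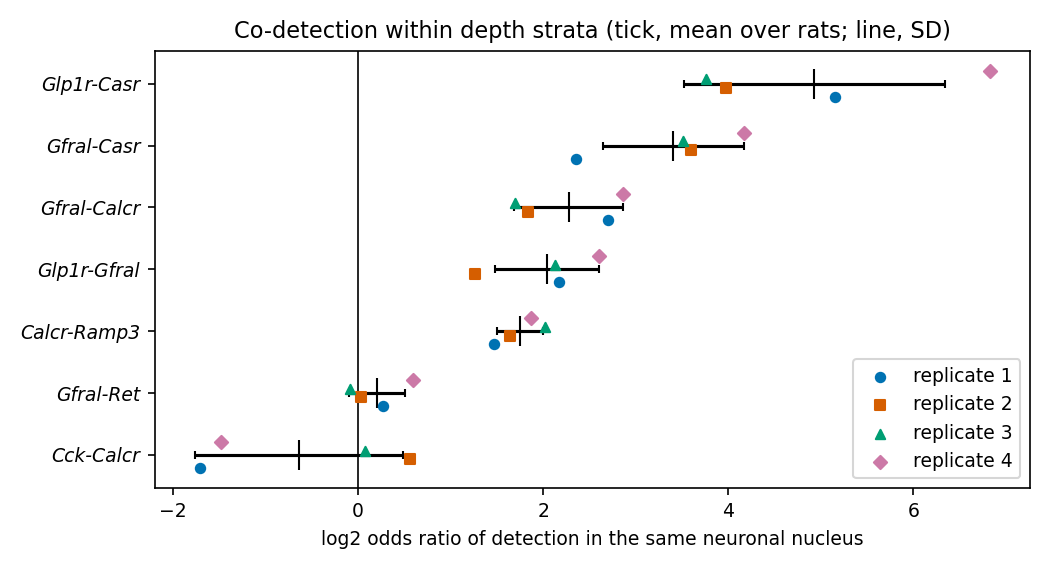
Log2 odds ratio of joint detection for 7 pairs of genes, with a point for each of 4 rats; 0 means independent detection at equal depth. Glp1r with Casr has the highest mean, 4.93, and Cck with Calcr the lowest, −0.64.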

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

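No test in this part was planned for these results, and no explanation was weighed for them. Each value below belonged to 1 rat that stood apart from the other 3 by more than Dixon's 95% critical value, which chance does in about 1 in 20 groups of 4. Of 127 sets of 4 values looked at, 7 met this limit: 6 of 80 sets of named genes, 1 of 14 class shares, and 0 of 7 co-detection values, 7 depth measures, 13 levels and 6 shares of neuron types.

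Endothelial-like nuclei made up 0.329% of the nuclei of replicate 2, below the 0.733% to 0.777% of the other rats. Myh6, a cardiac-type myosin heavy chain gene, had a log2 ratio of neurons to astrocyte-like nuclei of −4.14 in replicate 2, against −5.36 to −5.17 in the other rats. Its value was −5.79 (SE 0.30) with all rats and −6.09 without replicate 2. Klhl14 had a log2 ratio of inhibitory-like to excitatory-like neurons of 3.48 in replicate 4, against 3.05 to 3.12 in the others, and its level was 112 ± 14.7 CPM in inhibitory-like and 11.8 ± 1.74 CPM in excitatory-like neurons.

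Sec14l5 had a log2 ratio of oligodendrocyte-like nuclei to precursors of 4.73 in replicate 4, against 8.19 to 8.49 in the other rats. Its 2 counts in precursors both came from replicate 4, which makes the ratio 118 (95% interval 32.7 to 976). Without replicate 3 the ratio of Sec14l5 was 76.4 (21.15 to 631). Without replicate 4 Sec14l5 had 0 counts in precursors and was at least 61.9-fold higher by the limit of 3 counts. The log2 ratios of rats with 0 counts depend on the 0.5 CPM added to both sides.

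In the Gfral-rich cluster 3 genes were seen with 1 count each, and each count set 1 rat apart. The log2 ratio to other neurons of Drd2 was −3.18 in replicate 3, against −5.79 to −5.43 in the other rats. Those of Tfec and Oprd1 in replicate 1 were −2.43 and −2.37, against −5.70 to −5.34 and −5.51 to −5.09. Over the summed counts Drd2 was higher in other neurons by a ratio of 24.2 (95% interval 4.34 to 956), Tfec by 22.3 (4.00 to 880.3) and Oprd1 by 19.4 (3.49 to 768). Without the rat that held the count, 0 counts were left in the cluster, and by the limit of 3 counts Drd2 was at least 4.53-fold, Tfec at least 5.46-fold and Oprd1 at least 4.59-fold lower there. Without replicate 3 the ratios of Tfec and Oprd1 were 12.7 (2.27 to 500.1) and 11.3 (2.03 to 446). The log2 ratios of the rats with 0 counts depend on the 0.5 CPM added to both sides and are no measured folds.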

How the results depend on the processing

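Alternatives added after seeing the data were the mitochondrial limit of 10%, the removal of clusters missing from 2 or more rats, free RNA subtracted by Ttr, and library sizes alone. Named genes kept their direction and side of the threshold in 4280 cases over contrasts and settings, with 134 weaker and 4 reversed. Gene lists did so in 864 cases, with 53 weaker and 9 stronger, and panel genes in 329, with 12 weaker, 5 stronger and 2 reversed. Class shares moved by less than 1 SD in 133 cases and by more in 21, levels in 132 and 11, and co-detection in 50 and 2. The cause of each change below was not tested unless stated. Over all neurons the levels of some genes, such as Gcg, Pomc and Mc4r, lay below those of empty droplets, so free RNA may have brought part of them.

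Counts of called genes were within 1.5 times the first value except as follows. DESeq2 called 650 genes between inhibitory-like and excitatory-like neurons (first value 1552) and 688 in the Gfral-rich cluster (1039). Dropping the pairing by animal (no replicate block) gave 644 for the first, 41.49% of its 1552 calls, and changed no other count by so much. A minimum of 2000 UMIs gave 1294 for oligodendrocyte-like nuclei (1994), with 3112 in place of 4340 genes tested. The panel had 47 calls without a count filter, with 67 receptors tested, and 27 with the limit of 10%. Leaving out each rat gave 3290 to 3995 genes for neurons against astrocyte-like nuclei, 1008 to 1508 for inhibitory-like neurons, 1744 to 2026 for oligodendrocyte-like nuclei, 709 to 933 for the Gfral-rich cluster and 11 to 17 panel receptors. At a resolution of 2, 55.93% of the calls between inhibitory-like and excitatory-like neurons were made again and 24 were opposite. With free RNA subtracted by Ttr 73.54% of the calls of neurons were, with 82 opposite, and 77.2% of those of oligodendrocyte-like nuclei, with 80 opposite.

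With an estimated correlation 0 lists were called in each contrast (9, 3, 4 and 5 with the preset one). Between inhibitory-like and excitatory-like neurons 5 lists were called at 2000 UMIs and 7 at a resolution of 2, and 3 in the Gfral-rich cluster with another division of the genes. Reversed values were those of Calca in neurons against astrocyte-like nuclei (−0.42; 0.24 with the limit of 10%, 0.60 by Ttr), Htr2c and Il1rap in inhibitory-like neurons (−0.22 and −0.51; 0.76 and 0.057 at a resolution of 2). In the panel Acvr1c was −0.56 with doublets kept and Ramp3 0.38 with the limit of 10%; their first values, 0.33 and −0.06, were not called.

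At 2000 UMIs the shares were 64.7% neurons, 3.87% astrocyte-like, 5.53% oligodendrocyte-like, 1.89% precursor-like, 0.130% microglia-like, 1.84% choroid plexus-like and 18.5% unnamed nuclei. With the limit of 10% they were 45.5% neurons, 8.24% astrocyte-like, 22.2% oligodendrocyte-like, 3.67% precursor-like, 2.22% microglia-like, 0.426% ependymal-like and 2.23% choroid plexus-like nuclei. With doublets kept they were 2.26% precursor-like, 1.78% choroid plexus-like and 17.2% unnamed, and at 500 UMIs 3.59% microglia-like. Precursor-like nuclei made up 2.40% at a resolution of 2 and 3.01% without the missing clusters, which gave 1.76% choroid plexus-like nuclei. Thinning moved the log2 odds ratio of Gfral with Calcr to 2.97 and of Calcr with Ramp3 to 2.27. Committed precursor-like, endothelial-like and mural-like nuclei were not named at 2000 UMIs or with doublets kept, and perivascular macrophage-like nuclei not at 2000 UMIs. Another division named no microglia-like or perivascular macrophage-like nuclei, and the limit of 10% no endothelial-like or mural-like ones.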

Other observations

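The tests of free RNA in granule-like nuclei (in these nuclei and over all neuronal nuclei), the stricter mitochondrial value and the splits of the samples were chosen after the result was seen. The other tests were written before. A test of free RNA on Gabrd (13.1-fold or more above neurons and empty droplets) was run and is not used, since that gene had been picked from the leading genes of the granule-like nuclei. The clusters described next were left unnamed by the marker sets, and their genes took no part in the clustering.

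An unnamed cluster of 603 nuclei (128, 112, 265 and 98 in replicates 1 to 4) was led by Slc22a3, Reln and Wif1, among others. Reln, which encodes the matrix protein reelin, stood at 3003 ± 392.6 CPM in the cluster and 116.5 ± 57.4 CPM in the other nuclei (n = 4). Wif1, an inhibitor of Wnt signalling, was at 859 ± 108 CPM, 37.6-fold above the other nuclei, and the platelet-derived growth factor gene Pdgfd at 844 ± 56.6 CPM, 28.6-fold above. Lmx1a, a LIM-homeobox gene of the roof plate, was at 330.5 ± 67.0 CPM (32.9-fold), and the organic cation transporter Slc22a3 at 289 ± 58.8 CPM (103-fold).

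Another unnamed cluster of 619 nuclei had Slco2b1 at 258 ± 38.4 CPM (27.1-fold above the other nuclei), the leukocyte phosphatase Ptprc at 161 ± 18.6 CPM (23.6-fold) and the cathepsin Ctss at 272 ± 101 CPM. Its median doublet score was 0.0995, against 0.0159 in microglia-like nuclei. The largest unnamed cluster, of 960 nuclei (282, 144, 22 and 512 in replicates 1 to 4), scored 0.354 for neurons and 0.350 for oligodendrocytes and is counted in neither share. Its median doublet score was 0.144, and its Hapln2 level was 571 ± 138 CPM, 2.41-fold above the other nuclei. A cluster of 200 nuclei had the Hedgehog effector Gli2 at 129.6 ± 5.22 CPM (10.2-fold) and the homeobox gene Dbx2 at 52.3 ± 10.5 CPM (12.9-fold), and a cluster of 137 nuclei had Dbx2 at 39.2 ± 7.72 CPM (9.52-fold).

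Cerebellar granule-like nuclei were found in replicates 1 and 3, with 211 and 1054 nuclei, and 7 clusters with 2160 nuclei in all held at least 10 nuclei in each of these 2 rats and under 10 in each of the others. Over neurons and granule-like nuclei together, the granule markers stood at 130.1, 17.7, 261 and 14.6 CPM in replicates 1 to 4, of which free RNA brought 14.1, 7.14, 32.5 and 6.19 CPM by the level of Ttr. The excess of replicates 1 and 3 over the other rats was at least 6.711 times what free RNA brought, which argues against free RNA alone; the markers' ratio of granule-like nuclei to empty droplets, 8.019 or more, fell short of the 10 set for that test. Cerebellar tissue in the samples stays open by the test set for it: the markers' level in empty droplets was 76.3, 36.0, 182 and 23.5 CPM in replicates 1 to 4, a lowest ratio of 2.119, between the bounds of 3 and 1.5. That test used the granule markers alone. Other clusters nearly confined to replicates 1 and 3 included a neuronal one (168, 7, 270 and 1 nuclei in replicates 1 to 4) and an astrocyte-like one (60, 2, 154 and 0). An unnamed one had Itpr1 and Ca8 among its leading genes (22, 0, 42 and 0 nuclei). Whether these clusters are cerebellar was not tested. The neuronal, inhibitory-like one and the astrocyte-like one stayed in the sums of their classes. With clusters missing from 2 or more rats removed, 4011 genes were called for neurons against astrocyte-like nuclei and 1712 for inhibitory-like against excitatory-like neurons. The rats formed 1 group, so no biological explanation was tested for this or the next patterns.

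Oligodendrocyte-like nuclei rose from 15.03% to 22.2% of nuclei under a mitochondrial limit of 10%. The Ttr level of the nuclei between 5% and 10% was 1.059 ± 0.0365 times that of the nuclei under 5%, so they held little more free RNA. This does not decide whether free RNA raised the share, because the comparison stays within 1 class. Free RNA was estimated at 38.6% of the UMIs of oligodendrocyte-like nuclei and 20.3% of those of neurons. The mitochondrial share of the nuclei between 5% and 10% was 7.20%, of which their free RNA gave 4.60 points. It lay 2.599 ± 0.960 points above what their free RNA gave, and 1.80 ± 0.138 points above the 5.40% that selection by the limit gave. Mitochondria attached to nuclei are therefore a candidate explanation, though a wider spread of the free RNA share between nuclei was not covered.

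Glp1r and Casr UMIs lay together in 21 neuronal nuclei, 16 of them in cluster 13. The median doublet score was 0.0212 with both genes and 0.0552 in the 135 nuclei with Glp1r alone, a difference of −0.03394. Doublets stay open all the same, because the barcodes with the highest scores had been removed before this comparison. Median depth also differed, at 2378 UMIs with both genes and 3754 UMIs with Glp1r alone. Free RNA is argued against, since it gave 0.4984 of the 21 nuclei. That both genes mark 1 cluster stays open, because the log2 odds ratio within clusters was 2.945 ± 2.42 over rats.

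Other splits of the 8 sums of each contrast were fitted with edgeR without the block. Of 35 splits, 1, the real one, gave as many calls: 3774 for neurons against astrocyte-like nuclei (highest other split 1), 644 for inhibitory-like neurons (37), 1752 for oligodendrocyte-like nuclei (0) and 892 for the Gfral-rich cluster (20). For the panel 1 of 100 assignments of class names did, with 16 receptors against 3. The classes came from clustering the same nuclei, so class names assigned at random would give fewer calls in any case. The assignments therefore do not decide whether chance gave the panel's calls, and the same holds for the splits of the 4 contrasts. The sums of the 4 contrasts pair by animal, and the 8 splits that part every pair are too few for a share under 0.05. Fitted with the block, the real one gave 3993, 1552, 1994 and 1039 calls and the highest other 0 in each contrast.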
